A study of Oryza sativa with 13 samples.

How the data were processed

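DNA methylation was profiled by methylated DNA immunoprecipitation and sequencing (MeDIP-seq), in which fragmented DNA is captured with an antibody against 5-methylcytosine and the captured fragments are sequenced. The material was developing rice seed, hand-dissected into embryo and endosperm at set numbers of days after pollination (DAP). The endosperm is the nutritive tissue that forms beside the embryo after double fertilisation. Per the labels, the series holds 13 samples of the cultivars Zhonghua11 (ZH-11, japonica) and 93-11 (indica), and the libraries were amplified for 15 PCR cycles and sequenced on an Illumina instrument. The 7 ZH-11 libraries were analysed, namely 3 of embryo (3, 6 and 9 DAP) and 4 of endosperm (2, 3, 6 and 9 DAP). The 6 samples of 93-11 were not analysed here. Each combination of tissue and stage was 1 library, so there were no replicates of a stage.

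The authors deposited 1 peak list per library, called on each library separately. Per the submitters' processing notes, Bowtie2 and MACS were used, with no roles given. Per the file headers, peaks were called with MACS 1.4.2 from aligned reads without a control library, with an effective genome size of 360 Mb, a p-value limit of 1e-05, 1 tag kept per position, a fragment size of 200 bp, a tag size of 41 bp and a local background taken over 10 kb. A tag is 1 aligned read. With no control, the background of each peak came from the same immunoprecipitated library, which can lower the score of peaks inside densely enriched stretches. The genome build and the alignment settings are not given in the sources used here. The deposited tag count of each peak is a whole number of reads, not scaled to the size of the library. The score deposited with each peak is the negative base-10 logarithm of its p-value multiplied by 10, so that the lowest score in the lists is 50. The fold enrichment deposited with each peak is the ratio of tags at the summit to the local background. Peak length and summit position, in base pairs, are also the authors' values per the file headers. Score and fold belong to a single peak and were used to describe or filter lists.

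Depth, as tags left after filtering per the file headers, was 8062289, 8231245 and 8423857 for embryo at 3, 6 and 9 DAP, and 6833917, 7268516, 7302523 and 7465986 for endosperm at 2, 3, 6 and 9 DAP. All 3 embryo libraries were deeper than all 4 endosperm libraries, so depth and tissue cannot be separated by grouping the libraries. Exact Clopper-Pearson intervals at 95% were computed for shares of peaks. Reads amplified by PCR without molecular identifiers are not independent molecules, so these intervals cover counting error only. Exact intervals for shares of regions and for ratios of region counts treat regions as independent. They too leave out the spread between libraries.

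Covered length was the number of bases inside the peaks of a library. Pairs of libraries were compared by the base-pair Jaccard index, the length covered in both divided by the length covered in either. Peaks of all 7 lists that touched or overlapped were merged into regions, and a library counted as present in a region with 1 bp of overlap. A region was called embryo-only when present in all 3 embryo and no endosperm library, endosperm-only when present in all 4 endosperm and no embryo library, and shared when present in all 7. RPM values were the tags of a library's peaks in a region divided by its filtered tags and multiplied by 1000000. Along the 12 chromosomes, 367 complete bins of 1 Mb were ranked by their covered length averaged over the 7 libraries and divided into 5 quintiles. They were also ranked by the embryo libraries alone, and by the mean covered length of the bins on either side. Chromosome ends were taken from the last peak in any list, and the unplaced sequences were left out of the bins.

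Embryo and endosperm means were compared by two-sided exact permutation tests over the 35 ways of labelling 3 of 7 libraries, which cannot give a p below 0.0571. Stages of a tissue stood in for replicates, so these p-values measure only the spread between stages. Counts of regions and the Jaccard difference were recomputed under each of the 35 labellings, 8 of which exchange labels only within the stages sampled in both tissues. Clustering of tissue-specific regions was tested with 1000 permutations of region classes within 1 Mb bins. The comparisons of covered length, Jaccard index, tissue-specific regions and kept shares, most alternative settings and the rule for named regions were fixed before the data were examined. The comparisons by peak score, chromosome bin, quintile, ranking of the bins, tag level in shared regions, stage order and neighbouring regions, the tests of median length, long peaks, median fold enrichment, depth and tag share, and a sign-flip test with the tissues paired by stage were chosen after seeing the data. The rule took the 5 longest embryo-only and the 5 longest endosperm-only regions. Alternatives were a score of 100 or more, equal numbers of highest-scoring peaks per library (32986, the shortest list), a fold enrichment of 5 or more, merging within 200 bp, presence by coverage of at least 0.5 of a region, an overlap of at least 0.5 of the earlier peak, the stages sampled in both tissues, and leaving out each library.

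Planned comparisons of genes, gene lists, annotated features, GC content and repeats were not made, because no genome sequence or annotation in the coordinates of the lists was used here. Regions are therefore given by chromosome, start and end as the lists give them, without genes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The region code was tested on simulated lists with 5000 regions and recovered 400 of 400 embryo-only, 100 of 100 endosperm-only and 3000 of 3000 shared regions, while other labellings gave 0 embryo-only regions. Of 193 simulated shared regions raised 4-fold in embryo, 193 were called at 2-fold, and 0 of 2807 unchanged ones were. The simulated regions were well separated, lost no peaks and were drawn at equal depth. They check the code and give no accuracy for the real lists.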

Results

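The lists compared here describe where methylated DNA was enriched in embryo and endosperm of 1 rice cultivar, ZH-11, during early seed development. There were 3 embryo libraries (3, 6 and 9 DAP) and 4 endosperm libraries (2, 3, 6 and 9 DAP), 1 for each tissue and stage. The design asks how methylation profiles differ between the tissues and between stages. Depth ranged from 6833917 filtered tags in endosperm at 2 DAP to 8423857 in embryo at 9 DAP.

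Embryo libraries had more and shorter methylation peaks than endosperm libraries. The number of peaks was 53381 ± 1867 (SD, n = 3) in embryo and 35625 ± 1785 (SD, n = 4) in endosperm, a ratio of 1.46 ± 0.0604 over the 3 stages sampled in both. Peaks covered 56.3 ± 1.04 Mb in embryo and 47.4 ± 1.18 Mb in endosperm, with ratios of 1.17 to 1.19 at the 3 stages. Endosperm peaks were longer, with a median of 1027 ± 59.3 bp against 881 ± 9.17 bp. Peaks of at least 3 kb held 8.67 ± 0.830 Mb in endosperm and 3.40 ± 0.748 Mb in embryo.

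Each of these differences was complete, with no overlap between the libraries of the tissues, and gave p = 0.0571 in the exact permutation test, the smallest p this design allows (0.0714 after Benjamini-Hochberg adjustment over the 10 measures tested). The median fold enrichment of peaks was 6.59 ± 0.102 in embryo and 6.41 ± 0.301 in endosperm and overlapped between tissues (exact permutation p = 0.514, adjusted 0.514). Embryo libraries were deeper by a ratio of 1.12 ± 0.0107, and 59.5% ± 0.475 of their tags lay in peaks against 55.6% ± 2.42 in endosperm. With equal numbers of highest-scoring peaks the covered-length ratio reversed to 0.863, since the endosperm peaks were longer.

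By stage, embryo had 51509, 53391 and 55242 peaks at 3, 6 and 9 DAP, covering 55.8, 55.6 and 57.5 Mb. Endosperm had 32986, 36511, 36871 and 36132 peaks at 2, 3, 6 and 9 DAP, covering 46.3, 46.8, 47.3 and 49.0 Mb. These lengths were 15.4% to 16.0% of the effective genome size in embryo and 12.9% to 13.6% in endosperm.

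**Figure D1:**
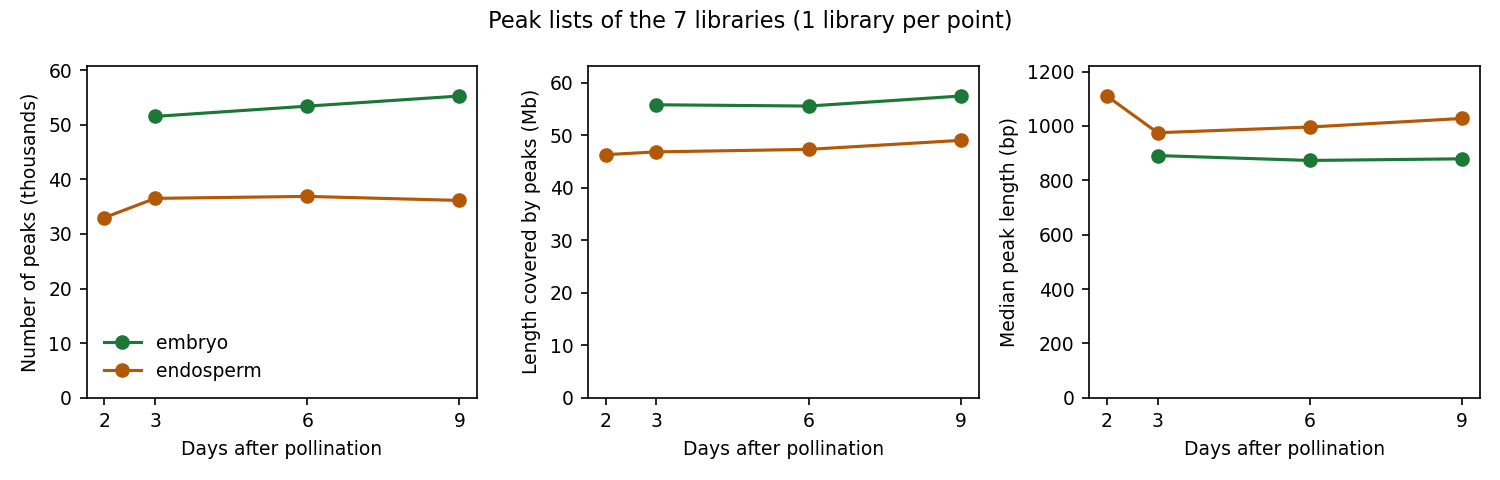
Number of peaks (in units of 1000), length covered by peaks (Mb) and median peak length (bp) against days after pollination, with 1 library per point and a line per tissue. Embryo libraries lie above endosperm libraries in number and covered length and below them in median length.

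Libraries resembled those of their own tissue more than those of the same age. The base-pair Jaccard index averaged 0.675 over the 3 embryo pairs and 0.619 over the 6 endosperm pairs, against 0.422 over the 12 pairs of different tissues. The lowest index within a tissue, 0.553 between endosperm at 2 and 3 DAP, was above the highest between tissues, 0.484 between embryo and endosperm at 3 DAP. Same-stage embryo and endosperm lists overlapped less at each later stage, with indices of 0.484 at 3 DAP, 0.436 at 6 DAP and 0.392 at 9 DAP.

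The mean index within tissues exceeded that between tissues by 0.216, and no other labelling of the libraries gave more than 0.115. Endosperm at 2 DAP was nearer to endosperm at 6 DAP, with an index of 0.631, than to endosperm at 3 DAP. It also had the lowest mean index with the 3 embryo libraries, 0.391, compared with 0.449, 0.428 and 0.419 for endosperm at 3, 6 and 9 DAP. There were no replicates to give these indices an error.

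**Figure D2:**
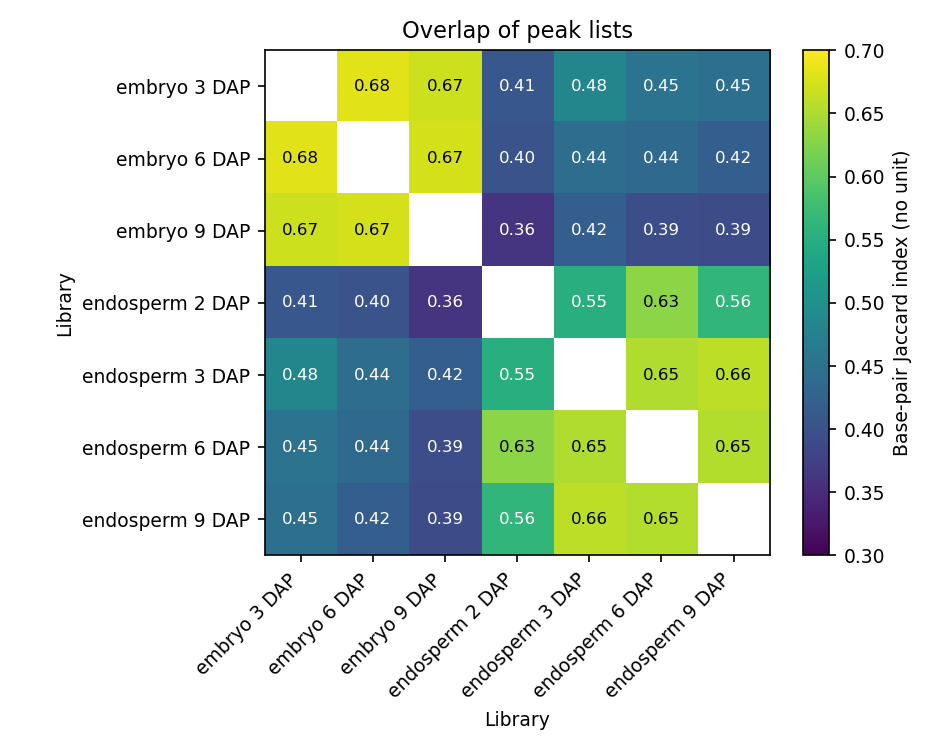
Base-pair Jaccard index (no unit) for each pair of the 7 libraries, with rows and columns ordered by tissue and stage. Pairs within a tissue run from 0.553 to 0.682 and pairs between tissues from 0.362 to 0.484.

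Methylation peaks found in 1 tissue at every stage were mostly embryo peaks. Of 70419 merged regions, 13715 (19.5%) were embryo-only and 1221 (1.73%) were endosperm-only, while 18550 (26.3%) were shared by all 7 libraries. Embryo-only regions covered 12.8 Mb with a median length of 850 bp, and endosperm-only regions covered 1.70 Mb with a median length of 1218 bp. Shared regions were longer, with a median of 1783 bp, and covered 39.9 Mb.

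No other labelling of the libraries gave more than 769 regions in 3 libraries alone or more than 735 in 4 libraries alone. With equal numbers of highest-scoring peaks there were 7350 embryo-only and 3641 endosperm-only regions, so the direction held while the ratio fell from 11.2 to 2.02. These ratios set a rule of 3 embryo libraries against a stricter rule of 4 endosperm libraries. Over the stages sampled in both tissues the ratio was 6.96, and 1.58 with equal numbers. With each of those stages also left out in turn, equal numbers gave 1.24 to 1.37. Leaving out endosperm at 2 DAP raised the endosperm-only count to 2053, and leaving out endosperm at 3 DAP raised it to 1930.

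The longest embryo-only region lay on chromosome 5 from 16820090 to 16827913 (7824 bp), with 80.1 ± 3.42 tags per 1000000 filtered tags (RPM, mean ± SD, n = 3). The next, on chromosome 6 from 28246371 to 28253882, had 56.3 ± 39.4 RPM, and its tags ran from 275 to 838 between the libraries. Chromosome 9 from 4725872 to 4732681 had 78.4 ± 11.5, chromosome 8 from 9510877 to 9517225 had 36.4 ± 30.5 and chromosome 11 from 4983369 to 4989612 had 47.8 ± 27.9 RPM. Tags ran from 149 to 577 in the chromosome 8 region and from 255 to 658 in the chromosome 11 region. The length of a merged region can be set by the peak of 1 library. The longest endosperm-only region lay on chromosome 9 from 6720339 to 6727307 (6969 bp), with 108 ± 11.7 RPM (SD, n = 4), and was 1 bp from the next merged region. The others were on chromosome 6 from 22759241 to 22765657 with 38.1 ± 23.5, chromosome 2 from 13327296 to 13333629 with 53.2 ± 15.5, chromosome 5 from 11795015 to 11800225 with 35.3 ± 16.8 and chromosome 2 from 13610732 to 13615836 with 53.2 ± 11.0 RPM. The other tissue had no listed peak in any of these 10 regions, which gives no tag number for it. These long regions had a low deposited fold enrichment. The local background, taken over 10 kb of the same library, can lower this value for long peaks, so it does not show weak methylation. Only the embryo-only region on chromosome 6 reached a fold enrichment of 5 in any library (4.44 to 5.49). The others ran from 2.43 to 4.65, below the lowest median fold enrichment of any list, 6.02.

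Even strong embryo peaks were often missing from endosperm of the same age, while strong endosperm peaks were nearly always present in the longer embryo lists. Among all peaks, 43.2%, 46.3% and 50.2% of embryo peaks at 3, 6 and 9 DAP had no overlapping endosperm peak, against 21.3%, 24.3% and 26.8% of endosperm peaks with no overlapping embryo peak. Peaks with a score of 300 or more were looked up in the whole list of the other tissue. Among them the shares were 22.7% (95% exact interval 21.7 to 23.7), 28.2% (27.2 to 29.3) and 33.0% (31.9 to 34.1) for embryo. For endosperm they were 0.867% (0.644 to 1.14), 2.36% (2.00 to 2.77) and 3.11% (2.61 to 3.67). The missing share rose with age in both directions and at each minimum score.

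When the other list was moved by 100 kb, 77.2% to 77.8% of embryo peaks and 67.2% to 69.0% of endosperm peaks lacked an overlap, so overlap by position alone also differed with the direction of the comparison. With equal numbers of highest-scoring peaks the mean missing shares were alike over all peaks, 42.5% for embryo and 42.5% for endosperm, as equally long lists nearly require. They differed again among peaks with a score of 200 or more, at 35.6% and 16.0%.

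**Figure D3:**
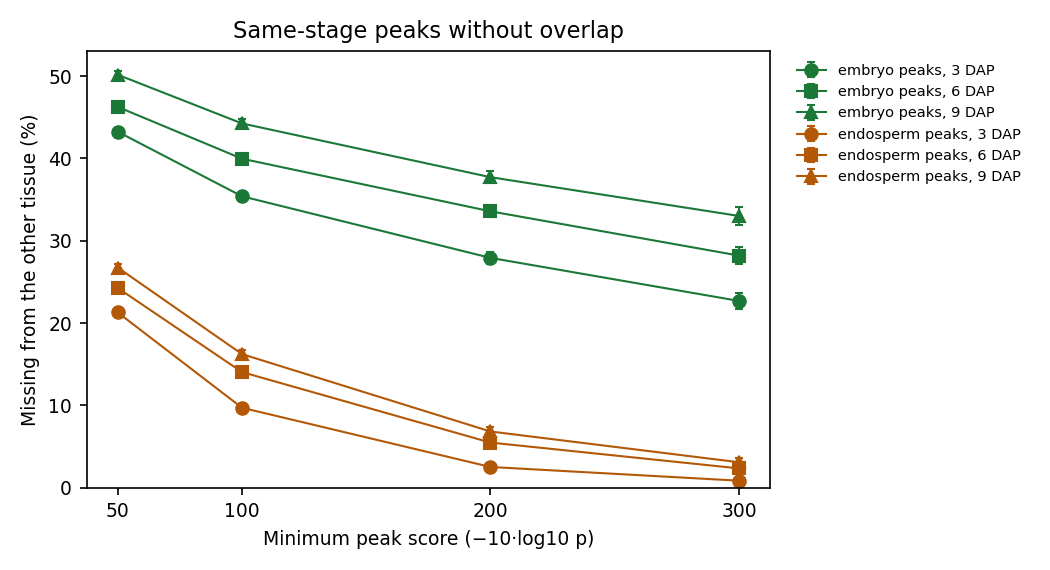
Share of same-stage peaks (%) with no overlapping peak in the other tissue against the minimum peak score, with a line per tissue and stage and bars for the 95% exact binomial interval. Embryo shares fall from 43.2% to 50.2% at a score of 50 to 22.7% to 33.0% at 300, and endosperm shares from 21.3% to 26.8% to 0.867% to 3.11%.

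Endosperm peak coverage fell below that of embryo by more in peak-poor than in peak-rich parts of the chromosomes. In the peak-poorest quintile of 1 Mb bins, embryo peaks covered 110 ± 3.88 kb per Mb (SD, n = 3) and endosperm peaks 73.0 ± 1.72 kb per Mb (SD, n = 4). The embryo to endosperm ratio was 1.50, 1.48, 1.31, 1.09 and 0.914 from the peak-poorest to the peak-richest quintile. In the richest quintile, endosperm covered 199 ± 7.02 kb per Mb and embryo 185 ± 5.78. Embryo-only regions made up 25.9%, 26.1%, 21.8%, 15.8% and 9.69% of the regions of the 5 quintiles, while endosperm-only regions stayed between 1.55% and 1.85%. With bins ranked by the embryo libraries alone the embryo-only shares were 21.7%, 24.2%, 20.7%, 18.0% and 13.5%.

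The tissues did not overlap in the 4 poorer quintiles (exact permutation p = 0.0571 each, the smallest possible, adjusted 0.0714 over the 5 quintiles), and in the richest quintile the exact permutation p was 0.114 before and after adjustment. The fall of the ratio from poor to rich quintiles was present under each of the 3 peak filters tried. Its crossing of 1 moved, with ratios from 1.14 to 0.628 at equal numbers of peaks and from 1.61 to 1.15 at a fold enrichment of 5 or more. The ranking of the bins used the coverage that was compared, which by itself lowers endosperm coverage in the poorer quintiles. With each bin ranked by its neighbouring bins the ratios were 1.45, 1.42, 1.31, 1.104 and 0.913, and with bins ranked by the embryo libraries alone, which acts against the difference, they were 1.31, 1.37, 1.23, 1.14 and 1.01.

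Every embryo library exceeded every endosperm library in 233 of the 367 bins, and the reverse held in 39, where chance gives 5.71% of bins for both directions together. The bins come from the same libraries, whose total covered lengths also did not overlap between tissues, so they are not independent of each other. The largest ratio, 2.94, was on chromosome 3 from 4000001 to 5000000, a bin with 87 embryo-only regions and 1 endosperm-only region. Embryo peaks covered 138 kb of it on average and endosperm peaks 46.9 kb. The next largest were on chromosome 9 from 20000001 to 21000000 (2.27), on chromosome 4 from 33000001 to 35000000 (2.11 in both bins) and on chromosome 3 from 28000001 to 29000000 (2.10). The lowest ratio, 0.695, was on chromosome 4 from 9000001 to 10000000, followed by 0.738 on chromosome 6 from 14000001 to 15000000 and 0.739 on chromosome 5 from 12000001 to 13000000. These bins were chosen after their values were seen. Whole-chromosome ratios ran from 1.06 ± 0.0252 for chromosome 12 to 1.38 ± 0.00534 for chromosome 3 (SD over 3 stages), and all 12 chromosomes were above 1 at each stage.

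**Figure D4:**
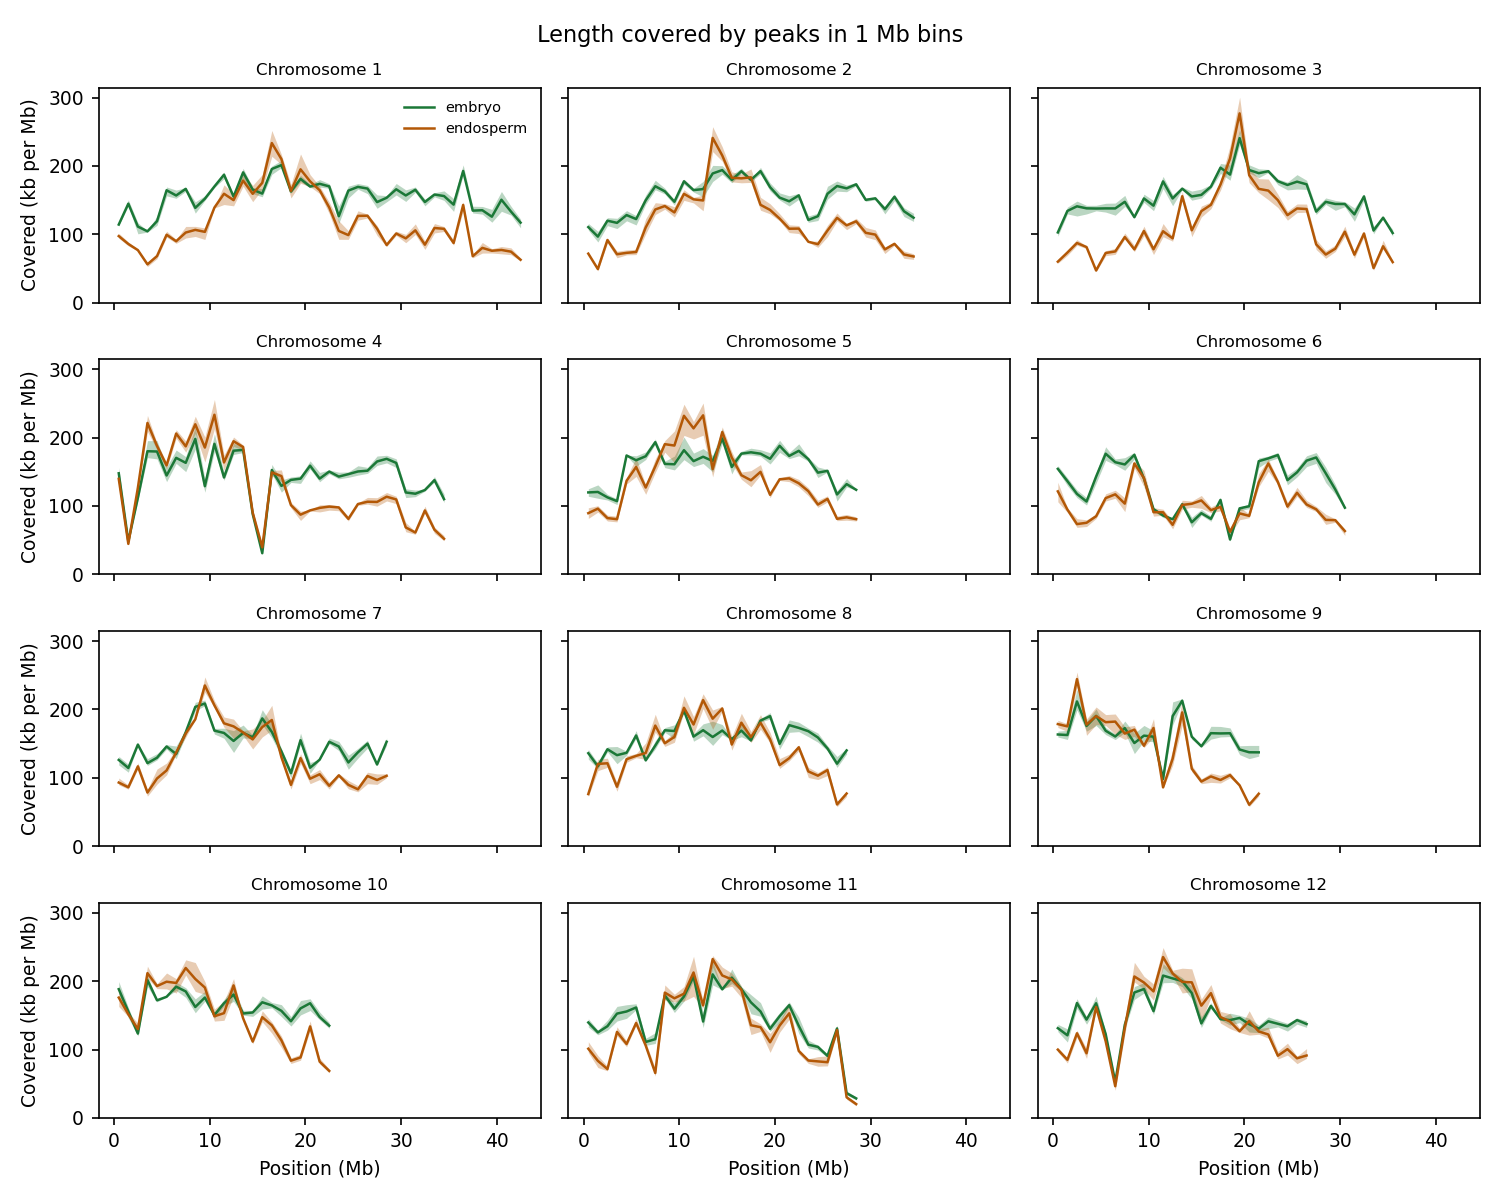
Length covered by peaks (kb per Mb) in 1 Mb bins against position (Mb) on the 12 chromosomes, with the mean of each tissue as a line and the range of its libraries as shading. Ratios of embryo to endosperm run from 0.695 on chromosome 4 to 2.94 on chromosome 3.

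**Figure D5:**
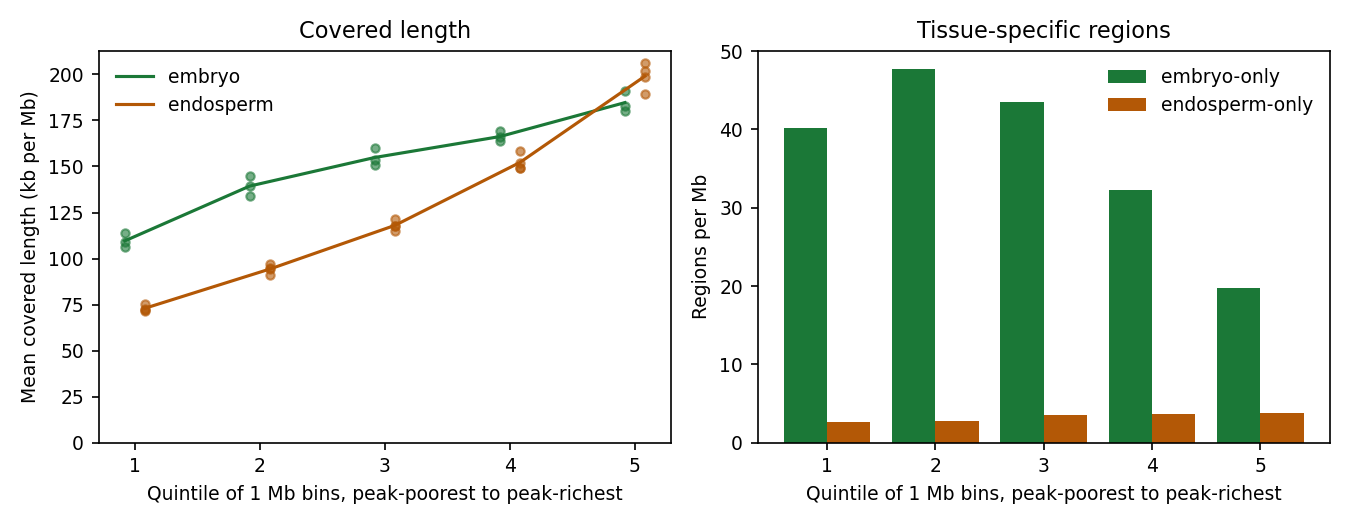
Mean covered length (kb per Mb, points for libraries and lines for tissue means) and number of tissue-specific regions per Mb (bars) in quintiles of 1 Mb bins from peak-poorest to peak-richest. Embryo-only regions number 40.2 per Mb in the poorest, 47.7 in the next and 19.7 in the richest quintile, and endosperm-only regions run from 2.61 to 3.76.

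Shared regions differed between tissues in tag level along the same axis. RPM values in the 18550 shared regions were lower in embryo by a median log2 difference of -0.28. At least 2-fold differences without overlap between the libraries were found in 999 regions higher in embryo and 1599 higher in endosperm. Relative to each library's median over shared regions, the numbers were 1393 and 1003, so the direction of the balance depends on the scaling. On either scale the share higher in embryo was lower in the peak-richest than in the peak-poorest quintile, 1.71% against 8.21% and, centred, 2.59% against 11.3%. The share higher in endosperm went the other way, from 5.57% to 12.3% and, centred, from 3.40% to 7.80%. With bins ranked by the embryo libraries alone these contrasts were smaller. The share higher in embryo was then 3.03% against 6.72% and, centred, 4.38% against 9.14%. The share higher in endosperm went from 6.96% to 10.4% and, centred, from 4.37% to 6.58%.

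Other labellings gave at most 597 regions higher in 3 libraries and 246 higher in 4, or 454 and 376 after centring. Without the 2-fold minimum, 16.4% of shared regions were higher in every embryo library and 33.4% in every endosperm library, or 21.0% and 24.3% after centring, where chance gives 2.86% each way. Tags were counted only inside called peaks, and these covered more of the shared regions in endosperm, 77.8% ± 1.69 (SD, n = 4), than in embryo, 73.9% ± 0.674 (SD, n = 3).

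Within a tissue most peaks persisted from stage to stage. Of the peaks of the earlier list, 88.2% (95% exact interval 87.9 to 88.5) were kept from 3 to 6 DAP in embryo and 87.7% (87.5 to 88.0) from 6 to 9 DAP. In endosperm 80.5% (80.1 to 80.9) were kept from 2 to 3 DAP, 84.3% (83.9 to 84.7) from 3 to 6 DAP and 82.7% (82.3 to 83.0) from 6 to 9 DAP. A peak was present at every stage in 40415 of the 60132 embryo regions (67.2%), over 3 stages, and in 22840 of the 45450 endosperm regions (50.3%), over 4 stages. With equal numbers of highest-scoring peaks the embryo shares, 83.6% and 82.7%, did not all exceed the endosperm shares, 76.9%, 83.2% and 83.0%, so the order of the tissues depends on the length of the lists.

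One-way gains outnumbered one-way losses, with 8782 regions gained and 5141 lost in embryo and 6943 gained and 4613 lost in endosperm. Depth also rose with age in both tissues. In embryo the order of the stages gave more one-way regions, 13923, than the other 2 orders of the libraries, 13173 and 12338. In endosperm it gave 11556, while an order with 3 and 6 DAP exchanged gave 13070. With 1 library per stage these changes have no replicate check.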

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

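The comparison in this part was found by reading the values of the libraries, and no test was run on it. From 3 to 9 DAP the median peak length moved in opposite directions in the tissues. It fell by 12 bp in embryo, from 891 to 879 bp, and rose by 52.5 bp in endosperm, from 975 to 1027.5 bp. At 6 DAP it was 873 bp in embryo and 996 bp in endosperm, so from 6 to 9 DAP it rose in both tissues. The difference was not tested, since each stage is 1 library. Endosperm at 2 DAP had the longest median, 1110 bp, so the later rise does not extend over all 4 endosperm stages. In the same libraries the length held in peaks of at least 3 kb was 4.25, 3.06 and 2.87 Mb in embryo at 3, 6 and 9 DAP. In endosperm it was 8.31 Mb at 3 DAP, lower at 6 DAP and 9.88 Mb at 9 DAP, so of the later libraries that at 9 DAP alone lay above that at 3 DAP.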

How the results depend on the processing

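Alternatives chosen after seeing the data were the restriction to peaks with a score of 200 or more, that restriction with equal numbers of peaks, equal numbers combined with the stages sampled in both tissues, bins without the richest quintile, ratios by quintile, other rankings of the bins, centring on shared regions, pairing by stage and leaving out both 3 DAP libraries. The within-tissue excess of the Jaccard index kept its direction and size under each alternative run, and the embryo-only count exceeded the endosperm-only count in each. Equal numbers of highest-scoring peaks reversed the covered-length ratio from 1.18 to 0.863 and the ratios of quintiles 3 and 4 to 0.978 and 0.779, gave 7350 embryo-only and 3641 endosperm-only regions, and brought the mean missing shares to 42.5% for embryo and 42.5% for endosperm. This follows from the construction, since embryo lists lost more of their peaks and the missing shares of equally long lists nearly have to match. With equal numbers and only the stages sampled in both tissues the counts were 7809 and 4935. Of 19 peak numbers, covered lengths and quintile ratios, 1 was kept at a score of 100 or more, 5 with equal numbers and 7 at a fold enrichment of 5 or more. Covered lengths and ratios were held to their spread, but peak numbers only to a wider fixed fold change. The 7 kept at a fold enrichment of 5 or more were all peak numbers, such as 42696 against 51509 in embryo at 3 DAP. The last setting turned the ratio of the richest quintile to 1.15, and ranking the bins by embryo alone turned it to 1.01 and moved the other 4. Of 5 ratios, 3 stayed within their spread with bins ranked by their neighbours.

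Without endosperm at 2 DAP there were 2053 endosperm-only regions, and without both 3 DAP libraries 2438. Each library left out removes a condition, to hold a peak or to lack one, and without embryo at 3 DAP alone the count was 1677. Leaving out each library in turn gave covered-length ratios of 1.17 to 1.18, Jaccard differences of 0.191 to 0.233, 14209 to 16553 embryo-only and 1405 to 2053 endosperm-only regions. With both lists of a pair filtered, missing shares for embryo and endosperm were 53.0% and 31.4% at a score of 100 or more. At a fold of 5 or more they were 54.9% and 30.9%. With only the peaks looked up filtered and the other list kept whole, they were 39.9% and 13.3% at a score of 100 or more. At a score of 200 or more these were 33.1% and 4.96%. For peaks with a score of 200 or more and equal numbers of peaks per list they were 35.6% and 16.0%.

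The shares of peaks kept from embryo 3 to 6 and 6 to 9 DAP and endosperm 2 to 3, 3 to 6 and 6 to 9 DAP moved outside their intervals. They were 85.3%, 84.1%, 75.8%, 82.4% and 76.0% at a score of 100 or more, and 85.5%, 83.1%, 75.8%, 80.6% and 71.3% at a fold of 5 or more. With equal numbers they were 83.6%, 82.7%, 76.9% and 83.2%, with 83.0% for the last inside its interval. With an overlap of at least 0.5 of the earlier peak they were 87.0%, 86.6%, 76.2%, 83.0% and 81.7%. The cause of these shifts was not tested. Embryo shares stayed above the endosperm shares under each setting except equal numbers, where embryo 6 to 9 DAP fell below endosperm 3 to 6 and 6 to 9 DAP. Paired by stage at 3, 6 and 9 DAP, the covered-length ratio of 1.18 gave p = 0.25 in a two-sided exact sign-flip permutation test, the smallest p that 3 pairs allow. The planned gene, gene list and feature alternatives were not run, since no annotation in the coordinates of the lists was used here. Depth may limit weak peaks most, which was not tested, and a missing peak is not a measured absence of methylation.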

Other observations

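The relabelling counts, equal numbers with libraries left out, the ranking of bins by their neighbours or by embryo, the comparison of endosperm at 2 and 3 DAP, the index with a fixed library, the clustering of regions and the combined alternatives in this part were chosen after the results were seen. Embryo-only regions lay next to each other more often than their density within 1 Mb bins gives. There were 3776 neighbouring pairs against 3153 ± 42.7 in 1000 permutations, with a one-sided permutation p of 0.001, the smallest these permutations can give. The longest run held 9 consecutive embryo-only regions on chromosome 3 from 4783313 to 4824014, a span of 40.7 kb inside the bin with the largest embryo to endosperm ratio. Runs of 8 lay on chromosome 2 from 32545361 to 32566213 and on chromosome 9 from 14911662 to 14937389. Endosperm-only regions formed 30 neighbouring pairs against 21.5 ± 4.60 (one-sided permutation p = 0.0470), and the single run of 3 lay on chromosome 5 from 3984257 to 3993214.

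Regions present in all 4 endosperm libraries and exactly 1 embryo library, 1167 in number, took embryo at 3 DAP in 38.6% (95% exact interval 35.8 to 41.5), at 6 DAP in 42.2% (39.4 to 45.1) and at 9 DAP in 19.1% (16.9 to 21.5). The embryo library at 9 DAP, the deepest, thus shared the fewest of these regions with endosperm. Of 3493 regions missing from a single endosperm library and present in all the others, 49.8% (48.2 to 51.5) were missing at 2 DAP, the shallowest library.

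Embryo-only regions outnumbered endosperm-only regions, 13715 to 1221. Of the 35 labellings of the libraries, 1, the real one, gave as many embryo-only regions (highest other 769) and 1 gave as many endosperm-only regions (highest other 735). That is the smallest share 35 labellings allow, counted in 1 direction under a rule set after the results were seen. A chance labelling is therefore not excluded. Exchanging labels only within the stages sampled in both tissues leaves 8 labellings, too few for a share under 5%, with highest others of 769 and 491. Weak peaks gained by the greater depth of embryo libraries stay open: at scores of 200 or more the missing share of embryo peaks was 6.67 times that of endosperm peaks (5.51 to 11.0 by stage), above the bound of 2 set in advance, but the embryo lists searched were also longer, and with equal numbers of peaks the ratio was 2.23 (2.00 to 3.05 by stage). Longer embryo lists as the whole source stay open too. With equal numbers the ratio stayed above 1, at 2.02 with all libraries and 1.58 over the stages sampled in both tissues. Its lowest value was 1.202 (exact interval 1.16 to 1.25) with 16493 peaks per library over those stages without 6 DAP. That interval counts regions as independent, although embryo-only regions clustered, and leaves out the spread between libraries. The cut to equal numbers kept a smaller part of the longer embryo lists than of the endosperm lists. It cannot decide whether longer lists were the whole source. In single same-stage pairs with equal numbers the mean missing shares of all peaks were alike, at 42.5% and 42.5%. Equally long lists nearly require this, so it bears on neither side. Longer lists as the source of a part of the excess cannot be told apart from a tissue difference, since 2.02 (exact interval 1.94 to 2.10) lay around a bound of 2 set in advance. A difference in methylation between embryo and endosperm, the contrast of the design, may account for a part of the excess and stays untested.

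Endosperm coverage was lower than embryo coverage in peak-poor bins, and the difference shrank towards the richest quintile, where its direction depended on the peak filter and the ranking (ratio 0.914 for all peaks, 1.15 at a fold enrichment of 5 or more and 1.01 with bins ranked by embryo alone). A few chromosomes with long peak-rich stretches are argued against as its origin, because 11 of the 12 chromosomes had a higher embryo to endosperm ratio in their peak-poorer bins when bins were ranked by their neighbours, the exception being chromosome 6 with 1.18 against 1.31. With bins ranked by embryo alone 10 did, with chromosome 5 as a further exception, which falls short of the bound of 11 set in advance. Peak calling against a local background cannot be told apart from a tissue difference, since the log2 tag ratio of shared regions was higher in the poorest than in the richest quintile by 0.31 (0.25 to 0.43 by stage), around a bound of 0.3 set in advance, and tags were counted only inside called peaks. A candidate explanation is lower methylation of peak-poor chromosome parts in endosperm, which may be tested with total methylation levels. That remains a hypothesis.

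Libraries resembled those of their own tissue, and 1 of the 35 labellings, the real one, gave a within minus between Jaccard difference of 0.216 (highest other 0.115). This too is the smallest share 35 labellings allow, under a rule set after the results were seen, so a chance labelling is not excluded. Within stages the 8 labellings are again too few, with a highest other of 0.104. The overlap of same-stage lists fell from 0.484 at 3 DAP to 0.392 at 9 DAP. For these libraries endosperm age as the whole cause is argued against, though only under a rule set after the results were seen. With the embryo library fixed the index fell from endosperm 3 to 9 DAP by at most 0.418 of the same-stage fall (0.253 to 0.418 over the 3 embryo libraries). With the endosperm library fixed it fell from embryo 3 to 9 DAP by 0.0474 to 0.0644 over the 4 endosperm libraries, and with equal numbers of peaks it fell in both comparisons too. Each stage is 1 library and the indices have no error. Embryo age therefore cannot be told apart from other properties of the embryo libraries, such as their depth, which also rose with age. A steady loss of similarity with endosperm age as part of the fall stays open, since the mean index with embryo fell from 0.449 to 0.428 and 0.419 at 3, 6 and 9 DAP, and the departure from it, a difference of -0.0580 between endosperm at 2 and 3 DAP, rests on the single shallowest library. Incomplete parting of the tissues at 3 DAP stays open too, since endosperm at 3 DAP took 29.7% (95% exact interval 27.9 to 31.6) of the 2416 regions present in all embryo libraries and exactly 1 endosperm library, between the bounds of 25% and 50% set in advance, while endosperm at 9 DAP took 30.4%. A tissue difference that grows with age may also account for the fall and was not tested.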
